A study of Mus musculus with 24 samples.

How the data were processed

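RNA-seq libraries from mouse bone marrow-derived macrophages were used, 24 in all. Per the labels they were TruSeq RNA v2 libraries sequenced as single-end reads of 50 bp on a HiSeq4000, in 8 groups of 3. The groups combine TBK1-WT or TBK1-cKD with control or IKKe knockout, untreated or after 8 h of R837. Control and IKKe knockout are both written with a delta sign in the labels (∆control and ∆IKKe). Treatment was taken from the titles, as the protocol text naming 8 h of R837 stands on every record, the untreated ones included. Per the labels' protocols, the 3 replicates came from 3 individual mice, each an independent biological replicate. The same protocol text names wild-type C57BL/6N mice on every record, although the labels give 4 genotypes, and the strain that carried the altered genes is not given. The labels do not say which libraries of different groups share a mouse, so no pairing was used. The replicate numbers used here follow the order of the deposited records and carry no other meaning.

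The deposited count values are whole numbers of reads per Ensembl gene, made by the authors from reads aligned to GRCm38 with GSNAP, per the submitters' processing notes. The counting program, the annotation release and the read filters are not given in the sources used here. The deposited RPKM values equal the count per kilobase of the deposited gene width and by a library total. That total is larger than the sum of the gene counts in every file, and the difference is called the share of reads outside the gene counts. The RPKM values served this check alone. Each file held 52636 genes, 52403 of them with a symbol. The 233 identifiers without a symbol held 0.019% of all counts. No column of per-sample values was left unused (0 columns). The library kit does not mark strand, so genes that overlap or lie antisense to one another cannot be separated. Members of families with near-identical copies, among them H2-Q genes, Saa genes and Gbp genes, are likewise uncertain.

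Genes were filtered with filterByExpr of edgeR (minimum count 10, minimum total count 15), which left 14681 genes. All 24 libraries were fitted together with 1 mean per group, scaled by the trimmed mean of M values (TMM). The quasi-likelihood F test of edgeR 4.0.16 gave each p, adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The common biological coefficient of variation was 0.116, with 16 residual degrees of freedom. The standard error of a log2 change was taken from the log2 change and its F value. There were 16 comparisons: the R837 response in each genotype, the genotypes against TBK1-WT control untreated and after R837, the other pairs of genotypes after R837, 3 differences of R837 responses and the TBK1 by IKKe interaction after R837. Levels in log2 CPM (counts scaled to a common library size) are after TMM with an offset of 0.5. Levels in CPM are counts over the sum of gene counts of the library, without TMM, so their ratios differ from the fitted log2 changes. Where a group had 0 counts for a gene, the ratio was computed against a floor of 3 counts over the group and given as a lower bound. With 1 to 3 counts the ratio is given with its 95% counting interval. Depth, as the sum of gene counts, ran from 19.7 to 41.3 M per library. R837 replicate 2 of TBK1-cKD control had the fewest counts. It had 14226 genes with a count, while replicates 1 and 3 of its group had 17948 and 17592. Untreated replicate 2 of TBK1-WT IKKe knockout, with 20.3 M counts, had 18427. The cause was not tested, and values of weakly expressed genes in R837 TBK1-cKD control are less certain for it. Over genes in log2 CPM this replicate 2 correlated with replicates 1 and 3 of its group at r = 0.9803 and 0.9796, while those correlated with each other at 0.9975.

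The 28 gene lists were written before the data were examined, as were the comparisons, the tests of genes and lists, the choice of genes to name and the alternatives described as set in advance. Several tests of flagged results, named below, were chosen after the data were seen. The lists covered the IKK family and partners, inflammatory cytokines and chemokines, NF-kB feedback and target regulators, interferon-stimulated genes, type I and III interferon genes, immediate early and MAPK feedback genes, antimicrobial and immunometabolic effectors, cell death and inflammasome, p53 targets, cell cycle, cholesterol synthesis, LXR targets, glycolysis and HIF1 targets, NRF2 targets, ATF4 and unfolded protein response, autophagy and lysosome, MHC class II and costimulation, MHC class I presentation, macrophage identity, Toll-like receptor signalling, and markers of neutrophils, dendritic cells, mast cells and basophils, lymphocytes, erythroid cells and megakaryocytes, stromal cells and fibroblasts, and osteoclasts, with the mitochondrially encoded genes as the last. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Over the 207 called lists, the estimated correlation gave the highest adjusted p of all alternatives in 188 and another setting did in 19. Within each list, genes were also adjusted over the list alone.

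Genes were named by a rule. In each comparison the 8 genes of largest rise and the 8 of largest fall were eligible among those past the threshold, with an average of at least 2 log2 CPM and, for comparisons of 2 groups, with values that did not overlap. Symbols of predicted or unnamed genes were left out. Up to 4 members with the smallest p of each called list were added, and Tbk1, Ikbke, Tnf, Il6, Il12b, Il1b, Cxcl1, Nfkbia, Tnfaip3, Ifnb1, Cxcl10, Ifit1 and N4bp1 always. Fewer are printed than the rule gives, from the top of each part, except that 1 gene the rule gives is not reported here. Malat1, Neat1 and Xist, as an index of nuclear RNA, were chosen after their values were seen.

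The alternatives set in advance were DESeq2 1.42.0, scaling by relative log expression, no count filter, a strict filter of 1 CPM in 3 libraries, a fit of the compared groups alone, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. Of these, the estimated correlation, the other scaling, the filters, the compared groups, the surrogate variable and each library in turn applied to lists. Further alternatives were chosen after seeing the data: the nuclear RNA level (high or low, with a threshold at a mean of 7 log2 CPM) as a term, only the 14 libraries of high level, leaving out the 2 R837 libraries of high level, and leaving out those and the library of fewest counts. No scaling moved the median of all genes by more than 0.1 log2.

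The scripts were tested on simulated data before use. For untreated TBK1-WT IKKe knockout against control, 200 of 14681 simulated genes were changed, and the 30 genes of a raised list were changed by 1 log2 besides. Of the simulated genes, 14250 passed the filter. Every simulated library had the mean profile of untreated TBK1-WT control otherwise, with no R837 response and no division by nuclear RNA level. The rates therefore do not cover those features of the real data. The edgeR test recovered 38.8% of 67 genes changed by 0.5 log2, 68.7% of 67 changed by 1 and 97% of 66 changed by 2, and called 6 of 14020 unchanged genes. DESeq2 recovered 53.7%, 74.6% and 97% and called 27 unchanged genes. The voom test recovered 41.8%, 68.7% and 97% and called 6. With no gene changed, simulated for untreated TBK1-cKD, the 3 tools called 0, 2 and 0 of 14250 genes. The camera test gave a raised list of 30 genes an adjusted p of 4.34e-85 and called 0 of 20 unchanged lists. R 4.3.3, python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.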

Results

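RNA was measured in bone marrow-derived macrophages (BMDMs), which are macrophages grown in culture from mouse bone marrow. The 24 libraries fell into 8 groups of 3. By the titles of the records there were 4 genotypes, each untreated and after 8 h of R837 (imiquimod), a small molecule that activates Toll-like receptor 7. The genotypes combined TBK1-WT or TBK1-cKD with control or IKKe knockout. The series record calls cKD a conditional knockout and does not describe the allele. TBK1 and IKKe, encoded by Tbk1 and Ikbke, are the IkB kinase-related kinases named in the title of the series beside N4BP1 and caspase-8. The sum of gene counts per library lay between 19.7 and 41.3 M, with a median of 31.4 M and a 2.09-fold difference between the lowest and the highest. Of 52636 genes in each deposited file, 27584 had a count in any library and 14681 passed the count filter and were tested. Log2 changes are given with the standard error of the edgeR quasi-likelihood fit, levels with the SD of 3 libraries, and adjusted p values by Benjamini-Hochberg. In the 11 comparisons of 2 groups that called genes, 800 named genes passed the threshold and 796 of them had 3 libraries of one group all above the 3 of the other. The naming rule required this of the genes of largest change, so the number is no measure of chance. The exceptions were the 4 comparisons of Ikbke that involve the R837 libraries labelled TBK1-cKD IKKe knockout.

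Tbk1 (ENSMUSG00000020115) lies on GRCm38 chromosome 10 from 121546455 to 121586787. In untreated cells its level was 6.67 ± 0.03 log2 CPM in TBK1-WT control, 6.68 ± 0.02 in TBK1-WT IKKe knockout, 6.22 ± 0.03 in TBK1-cKD control and 6.48 ± 0.02 in the libraries labelled TBK1-cKD IKKe knockout. After R837 the levels in the same order were 7.02 ± 0.17, 6.91 ± 0.06, 6.66 ± 0.10 and 6.93 ± 0.14 log2 CPM. Tbk1 fell in TBK1-cKD control relative to TBK1-WT control, by -0.45 ± 0.07 log2 untreated (adjusted p = 0.000674) and by -0.36 ± 0.07 after R837 (adjusted p = 0.0037, 0.000121 to 0.291 over the alternatives). Against TBK1-WT control, the libraries labelled TBK1-cKD IKKe knockout did not pass the threshold for Tbk1, at -0.20 ± 0.07 untreated (adjusted p = 0.0925, 1.13e-05 to 0.276 over the alternatives; 0.000959 with the nuclear RNA level described below as a term) and -0.08 after R837 (adjusted p = 0.445). The labels do not say which exons were altered, so these RNA levels do not measure the loss of the protein.

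Ikbke (ENSMUSG00000042349) lies on chromosome 1 from 131254343 to 131279606. Its untreated level was 5.89 ± 0.01 log2 CPM in TBK1-WT control, 5.14 ± 0.03 in TBK1-WT IKKe knockout, 6.21 ± 0.05 in TBK1-cKD control and 6.31 ± 0.05 in the libraries labelled TBK1-cKD IKKe knockout. Levels after R837 were 8.10 ± 0.49, 6.24 ± 0.09, 7.92 ± 0.03 and 6.89 ± 0.98 log2 CPM. After R837, Ikbke fell by 1.92 ± 0.31 log2 in TBK1-WT IKKe knockout (adjusted p = 0.000987), but the same comparison fitted on its 6 libraries alone gave an adjusted p of 0.0548, the highest of its alternatives (lowest 3.6e-17). In untreated TBK1-WT IKKe knockout the change of -0.76 ± 0.30 was not called (adjusted p = 1, 2.3e-10 to 1 over the alternatives; 0.0018 with the nuclear RNA level as a term and 7.59e-09 on the 14 libraries of high level). Ikbke RNA was not lower in untreated cells of the libraries labelled TBK1-cKD IKKe knockout, where it was 0.42 ± 0.30 log2 above TBK1-WT control (adjusted p = 0.476, 1.28e-08 to 0.652 over the alternatives; 0.0021 with the term and 7.69e-08 on the 14 libraries). Untreated, Ikbke was thus lower in TBK1-WT IKKe knockout than in its control (5.14 against 5.89 log2 CPM). The libraries labelled TBK1-cKD IKKe knockout lacked such a fall relative to TBK1-cKD control (6.31 against 6.21). The labels do not say which exons of Ikbke were altered, so its RNA level alone does not settle that label, which is used here as given.

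After R837 the 3 libraries labelled TBK1-cKD IKKe knockout did not share one level of Ikbke. Replicates 1, 2 and 3 were at 6.28, 6.37 and 8.02 log2 CPM. The difference of the group from TBK1-WT control was -1.03 ± 0.30 (adjusted p = 0.0101, 6.04e-17 to 0.248 over the alternatives). It was -0.71 without replicate 1 of TBK1-WT control (adjusted p = 0.0536), -0.74 and -0.76 without replicate 1 or 2 of the group labelled TBK1-cKD IKKe knockout (adjusted p = 0.0599 and 0.0633), and -1.84 without its replicate 3. Relative to TBK1-cKD control the difference was -0.79 (adjusted p = 0.0449, 3.09e-17 to 0.261 over the alternatives). Without replicates 1, 2 or 3 of TBK1-cKD control it was -0.80, -0.80 and -0.77 (adjusted p = 0.0753, 0.0817 and 0.0817). Leaving out replicates 1 or 2 of the group labelled TBK1-cKD IKKe knockout gave -0.50 and -0.52 (adjusted p = 0.179 and 0.182), and leaving out its replicate 3 gave -1.59 (adjusted p = 1.74e-07). With the nuclear RNA level described next as a term, the 2 differences were -1.20 and -1.43. On the 14 libraries of high level the former was -0.63, which sets 1 R837 library of each group against the other (8.02 and 8.66 log2 CPM) and has no replicates. Among R837 libraries of low level, replicates 1 and 2 of the group were below replicates 2 and 3 of TBK1-WT control (7.78 and 7.86 log2 CPM). They were also below TBK1-cKD control (7.90 to 7.95). Within each level Ikbke was thus lower than in TBK1-WT control, with 1 library of each group at the high level. No direction for Ikbke in the whole group is reported beyond these values.

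**Figure D1:**
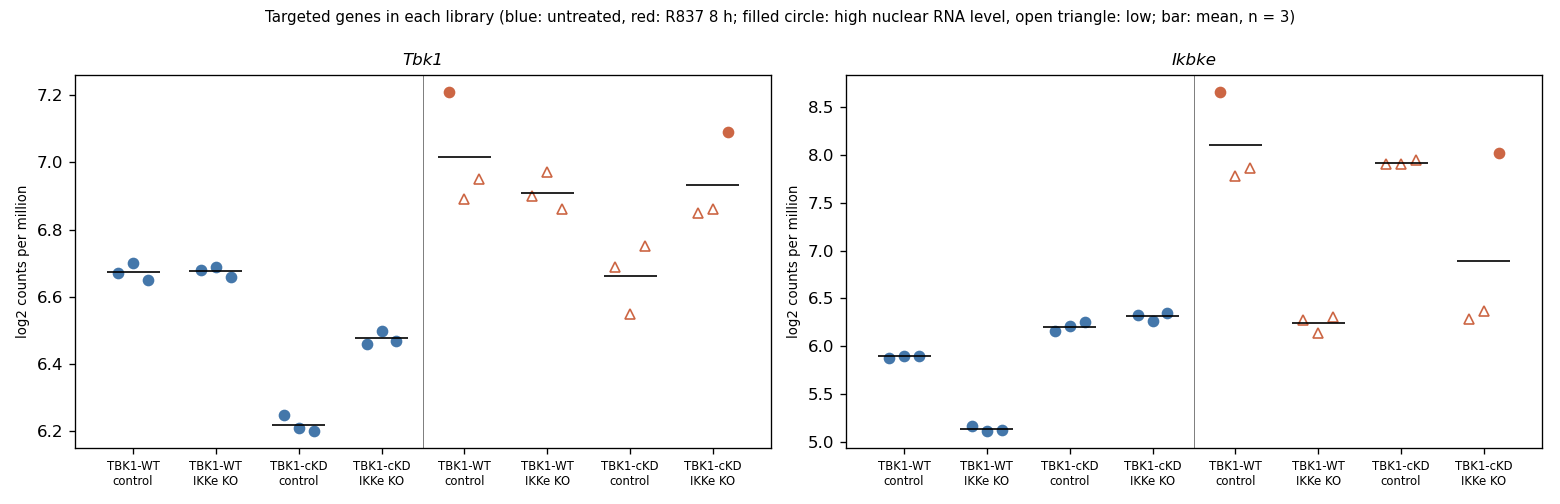
Tbk1 and Ikbke in each library, in log2 CPM on the vertical axis, by genotype, with untreated libraries in blue and R837 libraries in red. Filled circles mark libraries of high nuclear RNA level, open triangles those of low level, and bars are means of 3 libraries; Ikbke in the R837 libraries labelled TBK1-cKD IKKe knockout spans 6.28 to 8.02.

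A second property divided the libraries in a way the labels do not give. The mean log2 CPM of the nuclear RNAs Malat1, Neat1 and Xist was 8.92 to 9.62 in 14 libraries and 5.14 to 5.44 in the other 10. All 12 untreated libraries were at the high level, together with R837 replicate 1 of TBK1-WT control (8.92) and R837 replicate 3 of the group labelled TBK1-cKD IKKe knockout (8.93). The share of reads outside the gene counts, inferred from the deposited RPKM, divided the libraries in the same way, at 10.82 to 11.99% and 8.41 to 8.93%. Treatment and this level are thus largely confounded, and the TBK1-WT IKKe knockout and TBK1-cKD control groups hold no R837 library of the high level. Each comparison was therefore also fitted with the level as a term, and on the 14 libraries alone where both arms had one. Each R837 arm of the fit on the 14 libraries is a single library, so its spread comes from the untreated groups. For R837 groups with no library of the high level, the size of the term comes from the R837 libraries of high level in other groups. Some values of these fits are printed beside the results they change.

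**Figure D2:**
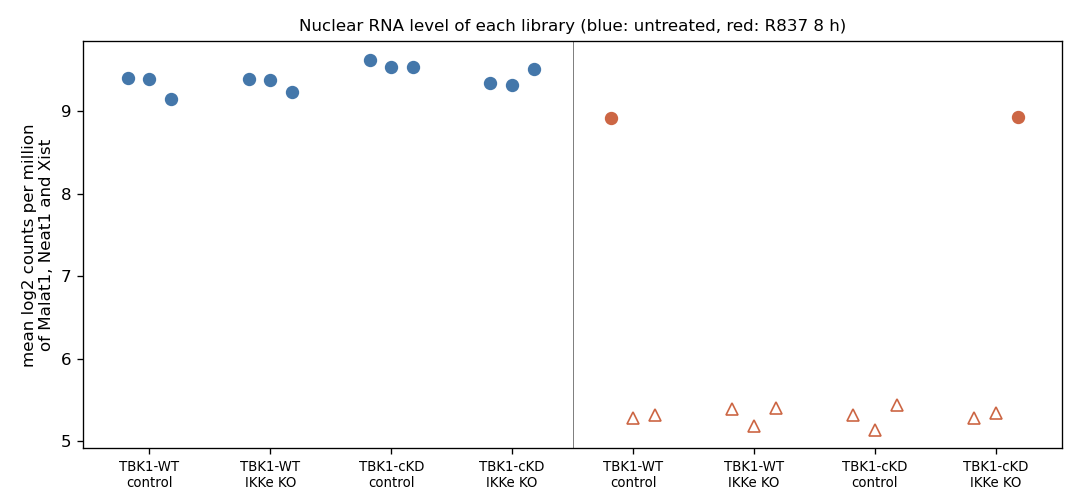
Mean log2 CPM of Malat1, Neat1 and Xist (vertical axis) in each of the 24 libraries by group, with untreated libraries in blue and R837 libraries in red. The 14 libraries at the high level lie between 8.92 and 9.62 and the other 10 between 5.14 and 5.44.

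The first question was how TBK1-WT control macrophages responded to R837. Il6, an inflammatory cytokine, had no count in untreated cells and rose at least 568-fold, to 16.2 ± 1.18 CPM. Il1b, the precursor of interleukin 1 beta, rose by 11.54 ± 0.20 log2 to 1580 ± 131 CPM (adjusted p = 1.26e-20), Cxcl1, a neutrophil chemokine, by 7.79 ± 0.15, and Tnf by 3.09 ± 0.08 (adjusted p = 3.34e-18). Nos2, the inducible nitric oxide synthase, had 2 counts in the untreated group and a ratio of 8640 (95% counting interval 2390 to 71300). Shisa3, the gene ranked first by rise, went from 0 counts to a level at least 1270-fold higher. Acod1, which makes itaconate, rose by 11.13 ± 0.16 (adjusted p = 2.88e-21), and the NF-kB feedback inhibitor Nfkbia by 4.06 ± 0.07. N4bp1 rose by 2.51 ± 0.06 (adjusted p = 1.49e-18), and Ikbke and Tbk1 by 2.27 and 0.35 (3.07 and 0.52 with the nuclear RNA level as a term; Tbk1 0.55 on the 14 libraries). Among the interferon-stimulated genes, Gbp2 rose by 4.45 ± 0.16, Cxcl10 by 3.70 ± 0.30 and Ifit1 by 2.69 ± 0.22. The strongest falls by rank were those of the transporter gene Slco2b1 (-6.81 ± 0.27) and Rasgrp3 (-6.75 ± 0.17, adjusted p = 2.14e-18). Intervals and bounds on ratios cover counting error only. Ifnb1 stayed under the count filter.

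R837 called 9189 genes in TBK1-WT control (4489 up, 4700 down; 62.6% of those tested), of which 1396 rose and 2362 fell by 2-fold or more. With the nuclear RNA level as a term the counts were 4371 up and 4418 down. Among lists of genes fixed in advance, 31 of 34 tested inflammatory cytokines rose and 1 fell, with a median log2 change of 3.10 (3.09 with genes at 0 set to their bounds). Of 34 NF-kB feedback and target regulators, 30 rose and 2 fell (median 2.08), and of 23 antimicrobial and immunometabolic effectors 22 rose (median 5.75). The camera set test gave adjusted p values of 6.6e-31, 4.25e-44 and 2.17e-60, and 4.84e-06, 3.98e-07 and 3.98e-07 with an estimated correlation. All 35 cell cycle genes fell, among them Mcm6 at -2.73 ± 0.08 (list median -1.76, adjusted p = 5.95e-20, 0.0077 with an estimated correlation). Adjusted over the list alone, these 4 lists gave the same numbers of calls.

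Calls of 7 further lists in this response depended on the correlation between genes. The interferon-stimulated list had 52 of 55 genes up and none down (median 1.39, adjusted p = 6.28e-13, 0.237 with an estimated correlation). The 12 genes of the IKK family and partners had 10 up (median 0.53, adjusted p = 0.000364, 0.0955 with an estimated correlation). Glycolysis and HIF1 targets had 21 up and 1 down of 26 (median 1.53, 2.66e-05 and 0.332), with Hif1a up by 2.31 ± 0.05. MHC class I presentation had 20 up and 1 down of 22 (median 0.87, 0.000119 and 0.255). Cholesterol synthesis had 16 up and 1 down of 24 (median 0.45, 0.0167 and 0.538), ATF4 and unfolded protein response 17 up and 7 down of 28 (median 0.55, 0.0193 and 0.255), and macrophage identity 15 up and 8 down of 28 (median 0.27, 0.0115 and 0.317), with Msr1 up by 2.97 ± 0.05. With the nuclear RNA level as a term, these last 3 medians were 0.20 (adjusted p = 0.197), 0.28 (0.0941) and 0.05 (0.033), and on the 14 libraries 0.22 (0.19), 0.32 (0.0597) and 0.01 (0.0427). The first value of each pair is the adjusted p at the preset correlation and the second that with an estimated one. The NRF2 target list (17 of 18 up, median 0.99, 1.07e-10 and 0.00861), the cell death and inflammasome list (16 up and 8 down of 28, median 0.47, 0.00138 and 0.028) and the Toll-like receptor list (18 up and 6 down of 31, median 0.34, 2.66e-05 and 0.00702) passed both. Adjusted over the list alone, cell death gave 9 down and Toll-like receptor signalling 7 down, and the other lists named in this paragraph gave the same numbers.

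The other lists were not called in this response or rest on few genes. Immediate early genes had 13 up and 12 down of 27 (adjusted p = 0.0868), p53 targets 6 up and 11 down of 23 (0.125), LXR targets 5 up and 4 down of 12 (0.947), autophagy and lysosome 11 up and 13 down of 36 (0.658) and MHC class II 7 up and 2 down of 15 (6 up over the list alone; 0.0696). Mitochondrially encoded genes had 5 up and 1 down of 12 tested (0.745). Of markers of other cell types, neutrophil genes had 4 up and 2 down of 9 (0.131), dendritic cell genes 1 up and 7 down of 9 (0.13), mast cell genes 1 up and 2 down of 5 (0.992) and stromal genes 3 up and 2 down of 13 (0.783). The osteoclast list had 3 up and 4 down of 11 (0.794), with a median of -0.08, a mean of 0.27 and an upward test direction. Lymphocyte markers had 1 up and 3 down of 6 (median -1.23, adjusted p = 0.0481, 0.111 with an estimated correlation, 0.0181 to 0.431 over the alternatives). Without replicate 1 or 2 of the R837 group the lymphocyte median was -0.99 or -1.22 (adjusted p = 0.109 and 0.0511), and with the nuclear RNA level as a term it was -1.67 (0.0941). The list of type I and III interferon genes had 0 of 19 genes tested and the erythroid list 4 of 15, with 2 up and 1 down, so neither had a list test.

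R837 responses in the other 3 genotypes had the same question. Il1b rose by 12.28 ± 0.20 log2 in TBK1-WT IKKe knockout, by 12.29 ± 0.21 in TBK1-cKD control and by 12.44 ± 0.20 in the libraries labelled TBK1-cKD IKKe knockout. Il6 ratios were 3140 (564 to 124000), 2210 (396 to 87300) and 6870 (1900 to 56700). Cxcl10, an interferon-stimulated chemokine, rose by 3.54, by 6.45 ± 0.35 (adjusted p = 9.52e-13) and by 1.80 ± 0.27 in the same order, and Ifit1 by 1.86 ± 0.22, 4.44 ± 0.24 and 1.99. Rasgrp3 fell in each, with -7.44, -6.92 and -8.70 ± 0.21. The 3 responses called 10300 genes (4751 up, 5549 down), 10148 genes (4645 up, 5503 down) and 9761 genes (4645 up, 5116 down). With the nuclear RNA level as a term these were 7965, 7711 and 9654. The rise of Ikbke depended on that term. It was 1.11, 1.71 and 0.82 in the 3 responses and 2.38, 2.99 and 1.45 with the term. TBK1-WT IKKe knockout and TBK1-cKD control hold no R837 library of high level. Their values with the term rest on the R837 libraries of high level in the other genotypes. Those libraries exceeded their group mates in Ikbke by 0.84 (TBK1-WT control) and 1.69 (labelled TBK1-cKD IKKe knockout), so 2.38 and 2.99 are uncertain. In the libraries labelled TBK1-cKD IKKe knockout the Ikbke rise was 0.01 without R837 replicate 3 (adjusted p = 0.956) and 0.79 without untreated replicate 2 (adjusted p = 0.0559).

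Inflammatory cytokines rose in 30, 30 and 33 of 34 genes in these 3 genotypes, with 1, 1 and 0 down and medians of 3.32, 3.37 and 4.46 (3.24, 3.03 and 4.11 with genes at 0 or near 0 set to their bounds). Their adjusted p values were 1.49e-32, 1.7e-32 and 1.02e-39, and 1.16e-05, 2.18e-05 and 1.73e-06 with an estimated correlation. All 35 cell cycle genes fell in each genotype (medians -1.92, -2.02 and -2.54; adjusted p = 2.33e-18, 1.74e-21 and 1.14e-22, and 0.0108, 0.00647 and 0.00551 with an estimated correlation). Interferon-stimulated genes had 41 up and 1 down in TBK1-WT IKKe knockout (median 0.89), 53 up in TBK1-cKD control (median 2.24) and 51 up in the libraries labelled TBK1-cKD IKKe knockout (median 1.67), of 55 tested. Their adjusted p values were 5.15e-06, 1.3e-24 and 3.69e-12 at the preset correlation and 0.423, 0.102 and 0.236 with an estimated one. Lymphocyte markers had 5 down of 6 in the libraries labelled TBK1-cKD IKKe knockout (median -1.94, adjusted p = 0.0198, 0.0575 with an estimated correlation), with Il7r at -2.20 ± 0.08 and Ighm at -2.94 ± 0.26, 1 up and 4 down in TBK1-WT IKKe knockout (median -1.53, 0.0338 and 0.0952) and 3 down in TBK1-cKD control (median -1.02, adjusted p = 0.0748). The first 2 gave adjusted p values of 0.0584 and 0.0535 with the nuclear RNA level as a term, and with no count filter medians of -0.52 and -0.18 (0.205 and 0.43). In the libraries labelled TBK1-cKD IKKe knockout the neutrophil list had 4 up and none down of 9, a median of -0.11 and a mean of 1.16 with an upward test (adjusted p = 0.0488, 0.111 with an estimated correlation, 0.00254 to 0.176 over the alternatives). Its median was 0.12 without R837 replicate 1, 0.07 without untreated replicate 3 and 0.06 without R837 replicate 3, -0.32 without R837 replicate 2, and -0.15 and -0.23 without untreated replicates 1 and 2, where the adjusted p was 0.0533 and 0.0501. With the nuclear RNA level as a term it was -0.23 (0.072), and on the 14 libraries 0.03 (0.00254).

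**Figure D3:**
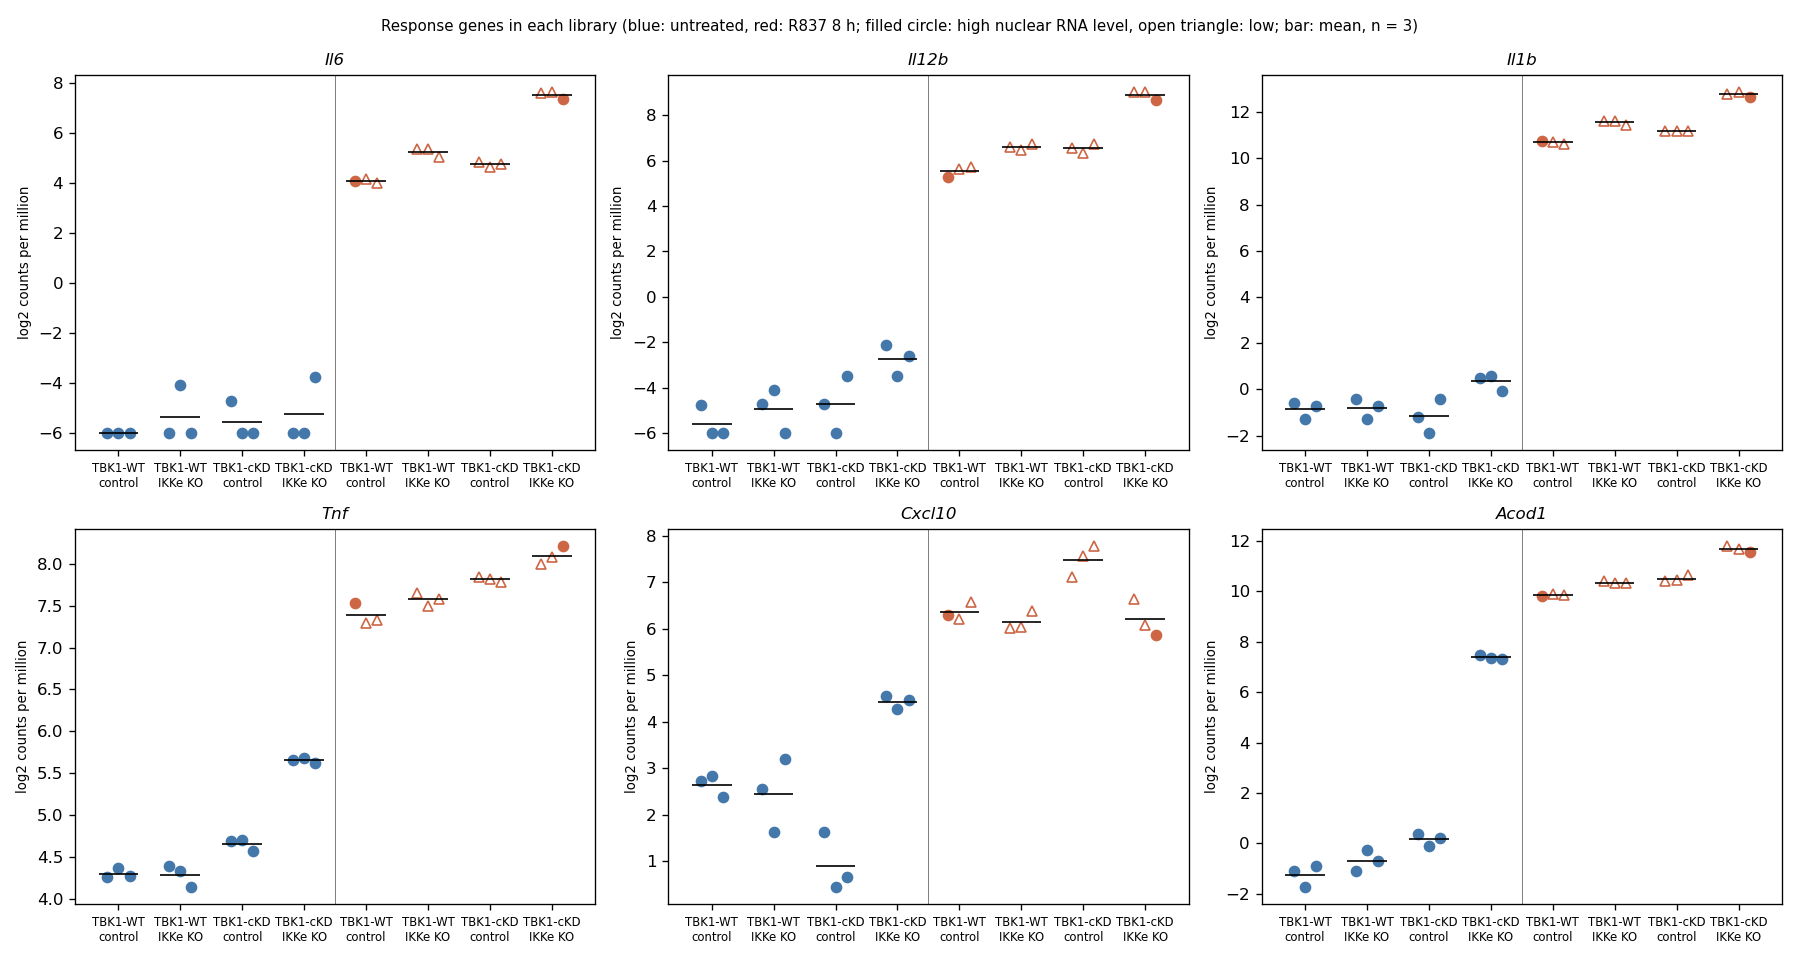
Il6, Il12b, Il1b, Tnf, Cxcl10 and Acod1 in each library, in log2 CPM on the vertical axis, by genotype, with untreated libraries in blue, R837 libraries in red and bars at means of 3 libraries. A library with 0 counts is drawn at -6 log2 CPM; Il6 after R837 reaches means of 16.2, 34.7, 24.4 and 152 CPM in the 4 genotypes.

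The effect of the IKKe knockout alone in untreated TBK1-WT cells was examined next. No gene passed the threshold by edgeR, while 422 genes had an unadjusted p under 0.05; DESeq2 called 1 and limma voom with quality weights 215. Without replicate 1 of the knockout group, edgeR called 5. With the nuclear RNA level as a term it called 3, and among the 14 libraries 10. Irf7 and Ifi44, both interferon-stimulated, were 0.81 ± 0.18 and 0.81 ± 0.19 log2 higher with an adjusted p of 0.709 each (Ifi44 0.82, adjusted p = 0.0134, on the 14 libraries). As a list, 55 interferon-stimulated genes moved up relative to other genes (median 0.37, adjusted p = 7.94e-47, 0.0279 with an estimated correlation), with no gene called over all genes and 21 up adjusted over the list alone. The median was 0.24 without replicate 3 of the knockout group. MHC class I presentation also moved up (median 0.19, adjusted p = 1.97e-20, 0.0279 with an estimated correlation; 7 up adjusted over the list alone), with H2-Q4 at 0.29 ± 0.07 (adjusted p = 0.744). Mitochondrially encoded genes moved down (median -0.22, adjusted p = 4.87e-07, 0.0279 with an estimated correlation; 4 down adjusted over the list alone).

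Other lists moved in the same comparison with no gene called. The glycolysis and HIF1 list had a median of 0.38 (adjusted p = 5.28e-20, 0.0817 with an estimated correlation; none up over the list alone), which was 0.59 and 0.22 without replicates 1 and 3 of the knockout group. Its members Egln3 and Slc2a1 were at 2.38 ± 0.73 and 1.01 ± 0.33 (adjusted p = 1 each), with SDs of 2.39 and 0.91 log2 CPM in the knockout group and 0.87 and 0.26 in control. NF-kB regulators had a median of 0.10 (adjusted p = 2.01e-06, 0.0279 with an estimated correlation; 1 up over the list alone), immediate early genes 0.09 (1.01e-06 and 0.100, 0.03 without replicate 1 of control) and cell cycle genes -0.10 (3.8e-05 and 0.156). The cell cycle median was -0.04 without replicate 3 of the knockout group (adjusted p = 0.0708). Cytokines (0.14, 0.00646 and 0.117), antimicrobial effectors (0.16, 0.00108 and 0.100), cell death (0.04, 0.00451 and 0.0717), LXR targets (0.07, 0.00659 and 0.100), MHC class II (0.14, 0.00423 and 0.112) and macrophage identity (0.06, 0.0471 and 0.453) passed at the preset correlation alone. Of these, the cytokine, antimicrobial, MHC class II and macrophage lists also lost the call in a fit without 1 library.

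The effect of TBK1-cKD in untreated cells was the next question. In TBK1-cKD control, interferon-stimulated genes fell, with Iigp1, an interferon-inducible GTPase, at -2.47 ± 0.27 (adjusted p = 7.87e-06), Ifi44 at -1.56 ± 0.20, Ifit1 at -1.15 ± 0.22 (adjusted p = 0.00278) and Cxcl10 at -1.60 ± 0.34 (adjusted p = 0.00519). Ly6a, also named stem cell antigen 1, fell by 3.68 ± 0.38 (adjusted p = 4.14e-06). Ccr2, a chemokine receptor of monocytes, fell by 1.65 ± 0.08 (adjusted p = 1.11e-10) and Tlr9 by 1.32 ± 0.11. Tnf rose by 0.36 ± 0.08 (adjusted p = 0.00525), Tnfaip3, the NF-kB feedback regulator A20, by 0.65 ± 0.08, Egr2 by 0.77 ± 0.10, Mmp9 by 1.57 ± 0.10 (adjusted p = 3.8e-09) and Eps8l1 by 2.04 ± 0.26. The comparison called 742 genes, 353 up and 389 down. The count was 418 without replicate 1 of TBK1-WT control, and 392 and 460 without replicates 2 and 3 of TBK1-cKD control. It was 2808 in a fit of the compared groups alone, 2042 with the nuclear RNA level as a term, and 2996 on the 14 libraries.

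Of the interferon-stimulated list, 34 of 55 genes fell in untreated TBK1-cKD control and none rose (50 down adjusted over the list alone; median -0.72, adjusted p = 7.15e-50, 0.0284 with an estimated correlation). Immediate early genes had 11 up (16 over the list alone; median 0.32, adjusted p = 3.87e-12, 0.029 with an estimated correlation). Inflammatory cytokines had 5 up and 1 down (7 and 3 over the list alone) and did not pass as a list (adjusted p = 0.0794). Glycolysis genes had 6 up (20 over the list alone; median 0.52, adjusted p = 1.09e-12, 0.123 with an estimated correlation). Markers of neutrophils were lower, with 5 of 9 down (5 over the list alone; median -1.82, adjusted p = 3.87e-12, 9.03e-05 with an estimated correlation) and S100a9 at -3.26 ± 0.39. That median was -1.04 without replicate 1 and -3.18 without replicate 2 of TBK1-cKD control. Stromal markers moved the same way, with 5 of 13 down (9 over the list alone; median -0.76, adjusted p = 3.81e-08, 0.0527 with an estimated correlation) and Col1a1 at -1.03 ± 0.22. The osteoclast list had 4 up (7 up and 1 down over the list alone; median 0.32, adjusted p = 8.75e-07, 0.00639 with an estimated correlation).

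The group labelled TBK1-cKD IKKe knockout was compared with TBK1-WT control in untreated cells. Acod1 rose by 8.67 ± 0.15 log2 (adjusted p = 8.43e-20), from 0.48 ± 0.143 CPM in TBK1-WT control to 182 ± 9.29 CPM in the libraries labelled TBK1-cKD IKKe knockout, without R837. The means in TBK1-WT IKKe knockout and TBK1-cKD control were 0.705 ± 0.214 and 1.24 ± 0.216 CPM. Nos2, with 2 counts in the control group, had a ratio of 530 (146 to 4380). Clec4e rose by 6.04 ± 0.14, Traf1 by 3.01 ± 0.08 (adjusted p = 2.78e-17), Ccl5 by 5.58 ± 0.25, Cxcl1 by 3.14 ± 0.18, Tnf by 1.35 ± 0.07 (adjusted p = 1.74e-11) and Nfkbia by 1.59 ± 0.06. Il1b rose by 1.20 ± 0.24 (adjusted p = 0.00121), Cxcl10 by 1.77 ± 0.29, Ifit1 by 1.37 ± 0.22 and N4bp1 by 0.79 ± 0.06 (adjusted p = 2e-09). Mmp9 rose by 4.92 ± 0.11 and the LXR receptor gene Nr1h3 by 1.89 ± 0.08. Cd24a fell by 2.91 ± 0.15 (adjusted p = 8.34e-12). In all, 2000 genes were called, 1251 up and 749 down, with 368 up and 161 down by 2-fold or more. Called genes numbered 5391 in a fit of the compared groups alone, 3752 with the nuclear RNA level as a term and 4910 on the 14 libraries.

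Antimicrobial and immunometabolic effectors had 18 of 23 genes up and 1 down in this untreated comparison (median 2.17, adjusted p = 1.91e-103, 6.86e-09 with an estimated correlation). NF-kB regulators had 24 up (26 up and 1 down over the list alone; median 0.66, adjusted p = 1.09e-57, 9.39e-08 with an estimated correlation). Inflammatory cytokines had 15 up and 1 down (adjusted p = 5.31e-09, 0.00296 with an estimated correlation), with a median of 0.35 that was 0.18 without untreated replicate 3 of the group. Interferon-stimulated genes had 50 of 55 up (51 over the list alone; median 0.78, adjusted p = 1.23e-31, 0.0355 with an estimated correlation), and MHC class II and costimulation 11 up (12 over the list alone; median 1.14, adjusted p = 5.34e-12, 0.000966 with an estimated correlation). The LXR target list had 9 up (median 0.47, 2.71e-10 and 0.000668). Cell cycle genes had 17 down (25 over the list alone; median -0.42, adjusted p = 1.02e-09, 0.0355 with an estimated correlation), among them Top2a at -0.65 ± 0.11. MHC class I presentation had 20 of 22 up (22 over the list alone; median 0.69, 9.81e-23 and 0.00657).

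Markers of other cell types also moved in this untreated comparison. Neutrophil markers had 2 up and 4 down of 9 (5 down over the list alone; median -1.57, adjusted p = 0.00308, 0.0179 with an estimated correlation, 0.273 on the compared groups alone), with Ngp at -4.71 ± 0.59, S100a9 at -4.01 ± 0.42 (adjusted p = 5.42e-07) and Ltf at -3.80 ± 0.45, while Mmp8 and Csf3r rose by 0.78 and 0.65. Stromal markers had 1 up and 7 down of 13 (9 down over the list alone; median -1.21, adjusted p = 3.06e-06, 0.0555 with an estimated correlation), with Col1a1 at -1.96 ± 0.23. The osteoclast list had 6 up and 1 down of 11 (7 up over the list alone; median 0.53, adjusted p = 5.34e-12, 0.000178 with an estimated correlation), with Acp5 up by 1.47 ± 0.08 and Ctsk by 1.03 ± 0.12. Dendritic cell markers had 1 up and 2 down of 9 (4 down over the list alone; median -0.26, adjusted p = 0.00631, 0.0355 with an estimated correlation), and lost the call with the nuclear RNA level as a term (0.0543) and on the 14 libraries (0.0639).

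After R837, the IKKe knockout was compared with control in TBK1-WT cells. Il6 rose by 1.16 ± 0.13 log2 (adjusted p = 4.46e-05), from 16.2 ± 1.18 to 34.7 ± 4.14 CPM, Il12b by 1.04 ± 0.14, from 44.6 ± 5.55 to 88.0 ± 8.20 CPM, and Il1b by 0.88 ± 0.12. Il1a, which encodes interleukin 1 alpha, rose by 1.44 ± 0.11 (adjusted p = 2.46e-07), Ptgs2, the inducible cyclooxygenase, by 1.31 ± 0.09 (adjusted p = 2.46e-08), Nos2 by 1.27 ± 0.12 and Il19 by 1.71 ± 0.28 (adjusted p = 0.00467). Cxcl1 rose by 0.71 ± 0.09, Tnfaip3 by 0.54 and Hif1a by 0.42 ± 0.05. The inflammatory cytokine list had 11 of 34 up and none down (22 up over the list alone; median 0.45, adjusted p = 4e-35, 3.91e-06 with an estimated correlation), the antimicrobial list 9 up (14 over the list alone; median 0.39, 2.67e-24 and 4.86e-05) and the NF-kB list 5 up (11 over the list alone; median 0.16, 2.85e-15 and 0.000234). Interferon-stimulated genes had no call over all genes or over the list alone, with a median of -0.17 (adjusted p = 0.000478, 0.737 with an estimated correlation). Called genes numbered 272, 168 up and 104 down, but 19 in a fit of the 2 compared groups alone, and 519 with the nuclear RNA level as a term. The count was 167 without R837 replicate 1 of control, and 125 and 143 without replicates 1 and 2 of the knockout.

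TBK1-cKD control was compared with TBK1-WT control after R837. Adam19 rose by 2.15 ± 0.09 log2 (adjusted p = 2.71e-12), Olr1 by 1.43 ± 0.15, Slc7a2, an arginine transporter gene, by 1.41 ± 0.11, Il1a by 1.12 ± 0.11 (adjusted p = 2.83e-06), Il12b by 0.99 ± 0.14 and Ptgs2 by 0.92 ± 0.09. Il6 rose by 0.66 ± 0.13 (adjusted p = 0.00327), Tnf by 0.43 ± 0.07, Cxcl1 by 0.55, Il1b by 0.50 (adjusted p = 0.00968) and Cxcl10 by 1.14 ± 0.26 (adjusted p = 0.00814). Ly6a fell by 2.70 ± 0.34 (adjusted p = 2.97e-05) and Bub1b, a mitotic checkpoint kinase gene, by 0.95 ± 0.13. Cytokines had 13 up and 1 down (14 and 1 over the list alone; median 0.34, adjusted p = 6.81e-09, 0.0134 with an estimated correlation), and cell cycle genes 1 up and 17 down (26 down over the list alone; median -0.46, adjusted p = 4.8e-10, 0.0455 with an estimated correlation). NRF2 targets had 7 up (10 over the list alone; median 0.29, 9.1e-07 and 0.0435). Interferon-stimulated genes had 7 up and 1 down (12 and 2 over the list alone; median 0.10, adjusted p = 0.00679, 0.744 with an estimated correlation). That median was -0.03 without R837 replicate 3 (adjusted p = 0.856) and 0.17 without replicate 1 of TBK1-cKD control (4.56e-06), and 0.07 without replicate 2 of TBK1-WT control (0.0873). Neutrophil markers had 1 up and 4 down (5 down over the list alone; median -2.21, 0.000719 and 0.0302), with S100a9 at -3.98 ± 0.44 and Ltf at least 13.4-fold lower. Stromal markers had 4 down of 13 (8 over the list alone; median -0.79, adjusted p = 0.000719, 0.214 with an estimated correlation) and the osteoclast list 5 up of 11 (6 over the list alone; median 0.36, 0.000145 and 0.0302), at 0.22 without R837 replicate 1 of TBK1-WT control and 0.21 with the nuclear RNA level and 0.15 with a surrogate variable as a term. Called genes numbered 1305, 657 up and 648 down, but 40 in a fit of the 2 compared groups alone, and 774 without R837 replicate 1 of TBK1-WT control.

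After R837, the group labelled TBK1-cKD IKKe knockout differed from TBK1-WT control in inflammatory genes. Il6 rose by 3.44 ± 0.14 log2 (adjusted p = 5.49e-13), to 152 ± 10.8 CPM, Il12b by 3.36 ± 0.15 (adjusted p = 3.05e-13), to 397 ± 41.3 CPM, and Il1b by 2.09 ± 0.12, to 5810 ± 248 CPM, in the libraries labelled TBK1-cKD IKKe knockout. Il1a rose by 4.91 ± 0.13 (adjusted p = 1.58e-16), Nos2 by 4.58 ± 0.14, Ptgs2 by 3.76 ± 0.09 and Cxcl1 by 2.40 ± 0.10. Tnf rose by 0.71 ± 0.07 (adjusted p = 7.71e-08), Tnfaip3 by 2.10 ± 0.08, N4bp1 by 0.66 ± 0.06 and Nfkbia by 0.37. Cxcl10 was not called, at -0.13 (adjusted p = 0.775). Clec4b1, a C-type lectin gene, fell by 3.73 ± 0.21 (adjusted p = 1.07e-11), Bub1b by 2.15 ± 0.14 and Aurka by 1.59 ± 0.10. In all, 4725 genes were called, 2447 up and 2278 down, of which 679 rose and 573 fell by 2-fold or more. A fit of the 2 compared groups alone called 2610.

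Cytokines had 31 of 34 genes up and none down in that comparison (median 1.80, adjusted p = 3.87e-42, 2.01e-06 with an estimated correlation), antimicrobial effectors 22 of 23 up (median 1.36, 1.12e-30 and 9.75e-06), and MHC class I presentation 21 of 22 up (median 0.93, 3.26e-20 and 0.0144), with the same numbers over each list alone. NF-kB regulators had 27 up and 3 down (28 and 3 over the list alone; median 0.55, 1.04e-18 and 7.54e-05). Interferon-stimulated genes had 44 up (48 over the list alone; median 0.95, adjusted p = 7.89e-21, 0.145 with an estimated correlation), with Gbp3 up by 2.27 ± 0.13 and Ifi205 by 3.27 ± 0.19. Cell cycle genes had 2 up and 28 down (median -0.86, 2.97e-17 and 0.0135). Stromal markers had 2 up and 7 down (10 down over the list alone; median -1.29, adjusted p = 0.00861, 0.328 with an estimated correlation), with Col1a2 at -1.97 ± 0.18. The osteoclast list had 5 up and 3 down (median 0.06, adjusted p = 0.0373, 0.182 with an estimated correlation), a call lost without R837 replicate 1 of TBK1-WT control (0.0776) or replicates 1 or 2 of the group (0.0553 and 0.0504). Neutrophil markers did not pass as a list (adjusted p = 0.986), with S100a9 at -4.18 ± 0.44 and S100a8 at 3.16 ± 0.18.

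**Figure D4:**
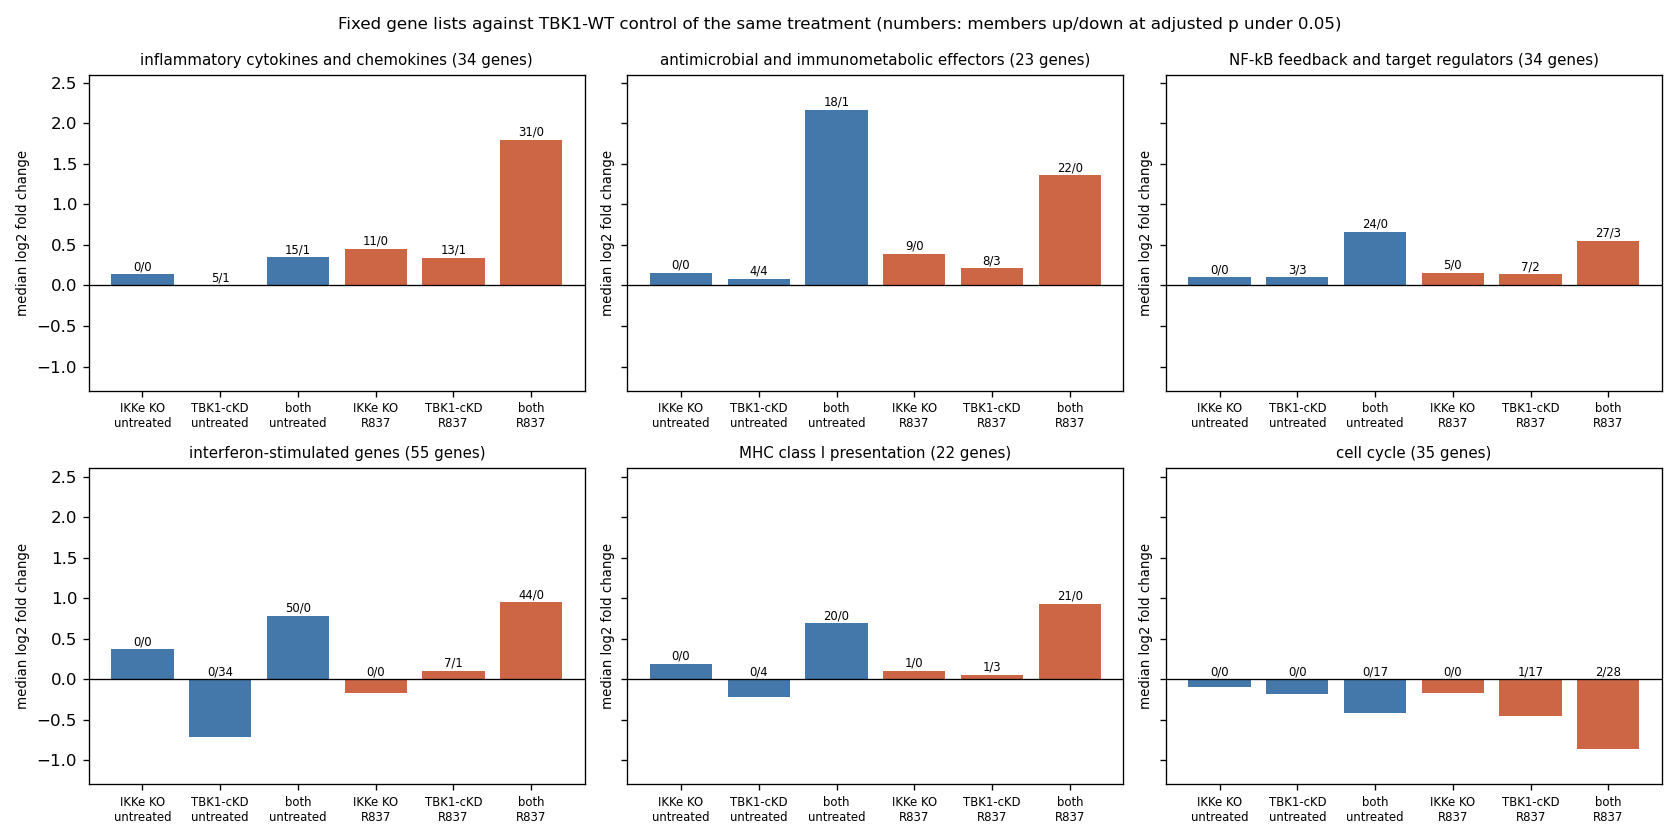
Median log2 change (vertical axis) of the genes of 6 lists in 6 comparisons with TBK1-WT control of the same treatment, untreated in blue and R837 in red, with the numbers of genes up and down written at each bar; both stands for the libraries labelled TBK1-cKD IKKe knockout. The cytokine list reaches a median of 1.80 in the libraries labelled TBK1-cKD IKKe knockout after R837 and the interferon-stimulated list a median of -0.72 in untreated TBK1-cKD control.

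The same R837 libraries were also compared with each single-genotype group. Relative to TBK1-cKD control, the libraries labelled TBK1-cKD IKKe knockout had Il6 up by 2.78 ± 0.13 log2, Il12b by 2.37, Il1a by 3.79 ± 0.12 (adjusted p = 1.16e-14) and Slamf1 by 4.83 ± 0.21, while Cxcl10 fell by 1.27 ± 0.26 (adjusted p = 0.000735). Relative to TBK1-WT IKKe knockout, Il6 rose by 2.28, Il12b by 2.32, Il1a by 3.47 ± 0.12 (adjusted p = 7.04e-14) and Slamf1 by 3.79 ± 0.19, and Ccr2 fell by 2.32 ± 0.09. Ifit1 rose by 1.06 ± 0.21 in the latter comparison (adjusted p = 0.00055), and Cxcl10 was not called, at 0.08. These comparisons called 5067 genes (2683 up, 2384 down) and 4498 genes (2417 up, 2081 down). The first count was 1864 in a fit of the compared groups alone. Cytokines had 27 up and none down (median 1.35, adjusted p = 8.06e-34, 2.61e-06 with an estimated correlation) and 28 up and 1 down (median 1.22, 9.92e-29 and 1.24e-05). Interferon-stimulated genes had 42 up and 2 down (43 and 2 over the list alone; median 0.80, adjusted p = 7.91e-19, 0.165 with an estimated correlation) and 51 up (52 over the list alone; median 1.15, 5.94e-36 and 0.0356). Relative to TBK1-WT IKKe knockout, stromal markers had 2 up and 7 down of 13 (median -1.19, adjusted p = 0.00443, 0.298 with an estimated correlation), with Col1a1 at -1.90 ± 0.24 and Sparc at -1.58 ± 0.19, and the osteoclast list 6 up and 1 down of 11 (2 down over the list alone; median 0.25, adjusted p = 0.0165, 0.122 with an estimated correlation), with Car2 up by 1.68 ± 0.22 and Ctsk by 1.09 ± 0.12. The osteoclast median was 0.38 and 0.14 without R837 replicates 3 and 1 of the group labelled TBK1-cKD IKKe knockout. Neither list passed relative to TBK1-cKD control (adjusted p = 0.325 and 0.809).

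Whether the change with R837 itself differed from that in TBK1-WT control was tested by interaction contrasts. For the IKKe knockout, Ptgs2 (1.37 ± 0.20 log2, adjusted p = 0.00199) and Gja1 (1.15 ± 0.18, 0.00386) rose more, as did the chemokine gene Ccl3 (0.65 ± 0.10, 0.00199). Called genes numbered 36, 19 up and 17 down, so 52.8% were up. DESeq2 called 122, of which 42.6% were up (52 up, 70 down). A fit of the compared groups alone called 23, and the nuclear RNA level as a term gave 146. The count was 22 and 20 without R837 replicates 1 and 2 of the knockout, 21 without its untreated replicate 2 and 17 without untreated replicate 2 of control. Interferon-stimulated genes responded less as a list (median -0.51, adjusted p = 2.35e-29, 0.101 with an estimated correlation), with no call over all genes and 29 down over the list alone.

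For TBK1-cKD control, interferon-stimulated genes changed more with R837 than in TBK1-WT control, from a lower untreated level. Cxcl10 was at 0.91 against 2.65 log2 CPM untreated and at 7.49 against 6.36 after R837. Ifit1 was at 3.67 against 4.86 untreated and at 8.13 against 7.55 after R837. After R837 the list of these genes was not called with an estimated correlation, as given above. Chance was not excluded for the number of genes called in this contrast, as described below. Cxcl10 differed by 2.75 ± 0.42 log2 (adjusted p = 0.00394), Iigp1 by 2.24 ± 0.34 (0.00394), Ifit1 by 1.75 ± 0.31 (0.00718) and Ifi203 by 1.09 ± 0.14 (0.00126). Lcn2, an iron-binding antimicrobial protein gene, differed by 3.01 ± 0.50 (0.00509), and Myc by -0.84 ± 0.13 (0.00394). The list had 23 of 55 up and none down (42 up over the list alone; median 0.82, adjusted p = 2.19e-64, 0.0202 with an estimated correlation). The cell death and inflammasome list had 3 up (4 over the list alone; median 0.11, adjusted p = 0.000115, 0.0202 with an estimated correlation), with Bcl2l11 at 0.50. Toll-like receptor genes had a median of 0.09 and a mean of -0.01 with an upward test (adjusted p = 0.0463, 0.243 with an estimated correlation). That call was lost without R837 replicate 1 of TBK1-WT control (0.04, adjusted p = 0.184) or its untreated replicates 1 and 3 (0.08 and 0.09, 0.0716 and 0.0567), and without untreated replicates 1 and 2 of TBK1-cKD control (0.09 and 0.07, 0.0548 and 0.0909) or its R837 replicate 3 (0.08, 0.135). The median was 0.14 without R837 replicate 1 of TBK1-cKD control, and 0.04 with the nuclear RNA level as a term (0.0592). Called genes numbered 129, 99 up and 30 down, but 29 in a fit of the compared groups alone, and 442 with the nuclear RNA level as a term. The count was 61, 66 and 62 without untreated replicates 1, 2 and 3 of TBK1-WT control, 47 and 72 without untreated replicates 2 and 3 of TBK1-cKD control, and 83 without its R837 replicate 3.

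For the group labelled TBK1-cKD IKKe knockout, Acod1 differed by -6.84 ± 0.18 log2 (adjusted p = 5.14e-16), Saa3 by -7.58 ± 0.58 (4.73e-09), Ccl5 by -3.76 ± 0.30, Clec4e by -4.48 ± 0.17, Nfkbia by -1.22 ± 0.09 (2.86e-09), Cxcl10 by -1.90 (0.00113) and Tnf by -0.64 ± 0.10 (9.71e-05). Each of these genes had a higher untreated level in this group than in TBK1-WT control. After R837 each but Cxcl10 (6.2 against 6.36 log2 CPM) was higher in this group too. Acod1 was at 7.4 against -1.24 log2 CPM untreated and at 11.69 against 9.86 after R837. The smaller rises thus started from a raised level. Slamf1 (4.47 ± 0.52), Ccl3 (1.91 ± 0.10) and Tnfaip3 (0.61, 0.000211) rose more in the libraries labelled TBK1-cKD IKKe knockout. Called genes numbered 2546, 1084 up and 1462 down, and 4420 with the nuclear RNA level as a term. The antimicrobial list had 5 up and 14 down (6 and 14 over the list alone; median -1.36, adjusted p = 3.8e-18, 0.000671 with an estimated correlation). Cytokines had 15 up and 7 down (17 and 8 over the list alone; median 0.90, adjusted p = 0.000163, 0.0648 with an estimated correlation). Interferon-stimulated genes had 6 up and 4 down (7 and 8 over the list alone; median 0.14, adjusted p = 0.276). The osteoclast list had 3 down (median -0.24, 0.000436 and 0.0472; -0.37 on the 14 libraries), with Mmp9 at -3.66 ± 0.14. Dendritic cell markers had 2 up and 1 down of 9 (3 up over the list alone; median 0.35, adjusted p = 0.0235, 0.121 with an estimated correlation), with Cd24a at 4.07 ± 0.24, Tcf4 at 0.40 and Batf3 at -1.56. That call was lost with the nuclear RNA level as a term (0.0898) and without R837 replicate 1 of TBK1-WT control (0.0595), and the median was -0.04 without untreated replicate 1 of TBK1-WT control (adjusted p = 0.0221). Batf3 was at -1.54 with that term, -2.01 without the 2 R837 libraries of high level and -0.83 on the 14 libraries. Cd24a and Tcf4 did not rise with R837 in the libraries labelled TBK1-cKD IKKe knockout. Cd24a was at 1.21 log2 CPM untreated and 1.22 after R837, against 4.11 and 0.08 in TBK1-WT control. Tcf4 went from 6.77 to 6.54, against 7.03 to 6.40 in TBK1-WT control.

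The last contrast asked whether the effect of TBK1-cKD after R837 differed between groups labelled IKKe knockout and control. Il6 differed by 1.62 ± 0.18 log2 (adjusted p = 6.68e-06), Il12b by 1.33 ± 0.19, Il1a by 2.35 ± 0.16 (5.67e-09), Cxcl1 by 1.13 ± 0.13, Tnfaip3 by 1.08 ± 0.10, Nos2 by 2.39 ± 0.17 and Ptgs2 by 1.52 ± 0.12 (5.31e-08), so that these genes were above the sum of the single-genotype effects. N4bp1 differed by 0.36 ± 0.08 (0.0037) and Ifi44 by 2.69 ± 0.26 (6.42e-07). The gene ranked first by rise was Neat1, at 6.28 ± 1.45 (adjusted p = 0.00479), which was 0.24 with the nuclear RNA level as a term, and 3.17 and 3.32 without the R837 libraries of high level in TBK1-WT control (replicate 1) and in the group labelled TBK1-cKD IKKe knockout (replicate 3). Other large rises also depended on those libraries. Clec2d, Firre, Lime1 and Pde1b differed by 5.04, 4.82, 4.53 and 4.53, and by 0, -0.3, -0.29 and -0.4 without both of them. Slamf1 kept its rise, at 3.74 with all libraries and 3.93 without both. Called genes numbered 3253, 1946 up and 1307 down, but 982 in a fit of the compared groups alone. The count was 1939 and 2090 without those libraries, and 2104 without R837 replicate 2 of TBK1-WT IKKe knockout. Cytokines had 21 up and none down (23 up over the list alone; median 1.03, adjusted p = 1.13e-14, 0.000632 with an estimated correlation), antimicrobial effectors 15 up (17 up and 1 down over the list alone; median 0.73, 1.44e-13 and 0.00139) and MHC class I presentation 17 up (19 over the list alone; median 0.70, 2.64e-19 and 0.0196). Interferon-stimulated genes had 43 up and 1 down (45 and 1 over the list alone; median 1.01, adjusted p = 1.21e-29, 0.0837 with an estimated correlation).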

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

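Several tests in this part were chosen after the result they measure was seen: the test of mixed untreated RNA, the fall of Malat1, Neat1 and Xist, the length bias, the position of R837 replicate 3 and both tests of Ikbke against the nuclear RNA level. The other tests were written before they were run, but those that use the nuclear RNA level rest on an index chosen after its values were seen.

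Interaction tests singled out genes whose R837 response or genotype effect differed between groups. Between TBK1-WT IKKe knockout and control, the R837 response differed for 36 genes. Between TBK1-cKD control and TBK1-WT control it differed for 129, with Cxcl10 at 2.75 log2 and Ifit1 at 1.75. For the libraries labelled TBK1-cKD IKKe knockout it differed for 2546 genes, with Tnf at -0.64, Nfkbia at -1.22, Tnfaip3 at 0.61 and Cxcl10 at -1.90. The effect of TBK1-cKD after R837 differed between groups labelled IKKe knockout and control for 3253 genes, with Il6 at 1.62, Il12b at 1.33, Il1b at 0.72, Cxcl1 at 1.13, Tnfaip3 at 1.08 and N4bp1 at 0.36. Tbk1 differed there by 0.39, and by 0.20 with the nuclear RNA level as a term.

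Some of these differences depended on single libraries or on the nuclear RNA level. For the response of the libraries labelled TBK1-cKD IKKe knockout, Il1b differed by 0.89. It was no longer called without untreated replicate 1 or 3 of TBK1-WT control (0.70 and 0.85, adjusted p = 0.195 and 0.0789), R837 replicate 3 of TBK1-WT control (0.85, 0.0501), or R837 replicate 2 or untreated replicate 3 of the group itself (0.84 and 0.71, 0.0512 and 0.1), or on the 14 libraries of high nuclear RNA level, with 1 R837 library per arm (0.72, 0.0758). Cxcl1 differed by -0.74 and was not called without untreated replicate 1 or 2 of TBK1-WT control (-0.63 and -0.78, 0.141 and 0.0532), its R837 replicate 1 (-0.68, 0.0559) or untreated replicate 1 of the group itself (-0.68, 0.0584), nor with the nuclear RNA level as a term (-0.74, 0.0723) or without the 2 R837 libraries of high level (-0.67, 0.14). Ikbke differed by -1.45, at -1.18 without R837 replicate 2 of the group (0.0503) and -2.26 without its R837 replicate 3 (1.11e-07). In the TBK1 by IKKe interaction, Cxcl10 differed by -1.06 and lost the call without R837 replicate 1 or 2 of TBK1-WT control (-1.02 and -0.99, 0.0714 and 0.0636), replicates 1, 2 or 3 of TBK1-WT IKKe knockout (-1.13, -1.12 and -0.94; 0.0575, 0.065 and 0.103), replicates 2 or 3 of TBK1-cKD control (-1.03 and -0.91, 0.0746 and 0.095) or replicates 2 or 3 of the group labelled TBK1-cKD IKKe knockout (-0.99 and -0.91, 0.0703 and 0.0949), and without the 2 R837 libraries of high level (-0.86, 0.0563). No group had 4 or more libraries, so the test for a single distant library in a group did not apply.

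Other splits of the same libraries gave these counts. For comparisons of 2 groups there are 10 splits, too few for a share under 0.05. The real split called most genes in 11 of the 12 comparisons, so that 1 of 10 splits reached its count; for untreated TBK1-WT IKKe knockout against control, 10 of 10 did, at 0 genes each. The highest other split called 0 genes except for TBK1-cKD control after R837 (12, real 1305), the group labelled TBK1-cKD IKKe knockout against TBK1-cKD control after R837 (112, real 5067) and the same group against TBK1-WT control after R837 (3404, real 4725). That last value came from a split that put both R837 libraries of high nuclear RNA level on one side. With the level as a term the real count was 6573. For the interaction tests, 25 splits including the real one were used. As many genes as the real 36 were called in 2 of 25 splits (highest other 49), as many as 129 in 4 (highest other 326) and as many as 2546 in 2 (highest other 2773), so chance was not excluded for these. Every split as large kept one arm as labelled; with both arms broken up the highest counts were 0, 0 and 463. For the TBK1 by IKKe interaction, 1 of 25 splits, the real one, reached 3253, with 1036 as the highest other. No smaller share is possible with 25 splits. Splits that mix genotypes also widen the spread within groups, which lowers their counts. Chance was therefore not excluded here either.

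R837 replicate 1 of TBK1-WT control and R837 replicate 3 of the group labelled TBK1-cKD IKKe knockout stood apart by their nuclear RNA level. Their deviations from the other replicates of their groups correlated at r = 0.94 over 10101 genes, against 0.07 at most among 9 pairs of other libraries. Untreated RNA mixed in, or a weaker response, was argued against: 381 induced genes were lower by a median of -0.12, while the share needed (87.2 and 90.7%) predicts -2.97 and -3.43. A library batch that differs in recovery of nuclear RNA stays open as the source. In these libraries, 37 lincRNAs exceeded coding genes of like width by 0.26 and 0.35 (at most 0.15 in 6 other R837 libraries). Both fell short of the excess set beforehand as a sign of such a batch. Of the 37, 25 and 27 were higher in the 2 libraries, and 25 in R837 replicate 1 of TBK1-cKD control, of low level. This test thus cannot tell a batch from other causes. No biological explanation was tested, as the labels give no difference between these libraries and their group mates.

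The nuclear RNA level also bears on what fell with R837. In TBK1-WT control, Malat1, Neat1 and Xist fell by 3.46 log2 without the 2 libraries and changed by -0.15 among the 14 libraries of high level. The high level was defined by these same RNAs, so the value of -0.15 was fixed by that choice. It cannot tell a library batch from an effect of R837 on these RNAs. As the whole cause of the fall of 3061 other genes a library batch was argued against, since these fell by a median of 1.27 among the 14 libraries (-1.27 against -1.73 without the 2). The tendency of longer genes to fall more had a Spearman rho of -0.07 among the 14 libraries and -0.23 without the 2, over 14775 genes, so a length bias of the batch may account for part of it. The high R837 arm of this test is a single library. An effect of R837 on nuclear RNA in the other libraries stays open, as treatment and level are largely confounded.

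Ikbke RNA was not lowered in the untreated libraries labelled TBK1-cKD IKKe knockout. Of the R837 libraries of that group, replicates 1 and 2 were at 6.28 and 6.37 log2 CPM and replicate 3 at 8.02. Replicate 3, of high nuclear RNA level, was above TBK1-cKD control after R837 (7.90 to 7.95, all of low level). It was below R837 replicate 1 of TBK1-WT control, of high level, at 8.66. These levels do not settle the label. The labels do not say which exons were altered, and untreated TBK1-WT IKKe knockout kept 39.7 CPM of Ikbke, with 68 CPM in control. A mislabelled R837 replicate 3 was argued against, since over 254 genes its median position between TBK1-cKD control (0) and the other replicates (1) was 0.93 (quartiles 0.74 and 1.09). Ikbke was 0.84 and 1.69 higher than in group mates in both libraries of high nuclear RNA level, so the spread may follow that level. Untreated libraries that are in truth TBK1-cKD control were argued against by 173 genes raised after R837, which were also higher untreated by a median of 0.73 (quartiles 0 and 2.34; 0.68 in the lowest library). That the high level alone hides a lower Ikbke in these untreated libraries (0.43 above TBK1-WT control) was argued against, since untreated TBK1-WT IKKe knockout, of the same level, was lower by -0.76 (adjusted p = 7.59e-09 among the 14 libraries).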

How the results depend on the processing

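Fits with the nuclear RNA level as a term, on the 14 libraries of high level, without the 2 R837 libraries of high level, and without these and R837 replicate 2 of TBK1-cKD control (3 left out) were chosen after seeing the data. The cause of the changes given here was not tested. No paired analysis was run because the labels do not say which libraries share a mouse, and the order of the records was not tried as a term.

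Scaling by relative log expression and the strict filter left all 16 counts of called genes within 1.5 times. For untreated TBK1-WT IKKe knockout, 0 genes became 1 by DESeq2, 4 without a filter, 215 by voom, 1 with a surrogate variable, 3 on the compared groups alone, 3 without the 2 libraries, 23 with 3 left out, 3 with the level as a term and 10 on the 14. For untreated TBK1-cKD control, 742 became 3584 by voom, 1313 with a surrogate variable, 2808 on the compared groups, 1914 without the 2, 3054 with 3 left out, 2042 with the term and 2996 on the 14. For the untreated group labelled TBK1-cKD IKKe knockout, 2000 became 5618 by voom, 5391 on the compared groups, 3607 without the 2, 4882 with 3 left out, 3752 with the term and 4910 on the 14.

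After R837, the IKKe knockout count of 272 became 499 by DESeq2, 975 by voom, 19 on the compared groups, 664 with 3 left out and 519 with the term. The 1305 genes of TBK1-cKD control became 40 on the compared groups. The 4725 of the group labelled TBK1-cKD IKKe knockout became 7129 by voom and 2610 on the compared groups, and its 5067 against TBK1-cKD control 1864. Of the differences of R837 responses, 36 became 122 by DESeq2, 431 by voom, 68 with a surrogate variable, 23 on the compared groups, 115 without the 2, 247 with 3 left out and 146 with the term; 129 became 266, 817, 29 on the compared groups, 382, 645 and 442; and 2546 became 5538 by voom, 4763 with 3 left out and 4420 with the term. The interaction count of 3253 became 1682 with a surrogate variable and 982 on the compared groups.

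Leaving out each library in turn gave 8203 to 10232 genes for R837 in TBK1-WT control, 9557 to 9742 in TBK1-WT IKKe knockout, 9434 to 10016 in TBK1-cKD control and 8981 to 10397 in the group labelled TBK1-cKD IKKe knockout. Untreated, the genotype counts were 0 to 5, 392 to 714 and 1458 to 1670. After R837 they were 125 to 356, 774 to 1729, 4249 to 5411, 4180 to 5317 and 3538 to 4774, and for the interactions 17 to 37, 47 to 142, 2086 to 3108 and 1939 to 4263. Of 120 such counts, 99 stayed within 1.5 times, 20 were lower and 1 higher.

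Named genes past the threshold changed direction in 2 comparisons. Neat1 against TBK1-cKD control after R837 was -0.28 with a surrogate variable. In the TBK1 by IKKe interaction, Clec2d was 0, -0.10 and -0.01 without the 2, with 3 left out and with the term. Firre was -0.41 by voom, -0.75 with a surrogate variable, and -0.30, -0.69 and -0.33. Lime1 was -0.01, -0.17, -0.29, -0.38 and -0.31 in the same order. Pde1b was -0.14 by voom, and -0.40, -0.34 and -0.42.

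Of 1164 named genes, 1158 stayed on their side of the threshold and in their direction under relative log expression, 1115 of 1153 under DESeq2, 1107 with the term and 1008 of 1154 on the compared groups. Of 207 called lists, 203 stayed called under relative log expression, 190 with a surrogate variable, 180 with the term and 88 with an estimated correlation. In leave-one-out fits, 1390 of 1464 list calls stayed. The least deep library had 19.7 M counts, and genes under the count filter, among them Ifnb1, were not tested.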
